A study of Homo sapiens with 10 samples.

How the data were processed

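Poly(A) RNA of 10 U2OS libraries was measured by sequencing after stranded library preparation. The cells carried 1 of 3 shRNAs against ARVCF or a negative control shRNA under puromycin selection at 1 µg/ml, and were untreated or given 10 µM nutlin-3a for 24 h. Per the submitters' processing notes, reads were made with bcl2fastq 1.8.3, aligned to hg38 with HISAT2 2.1.0 and scaled across libraries with Cuffnorm 2.2.1. The annotation behind the gene symbols is not given in the sources used here. The deposited table holds, per gene and library, a signal made by the authors: an estimated number of fragments scaled by a factor per library. These values are not whole counts, but between 51.6% and 58.2% of the positive values of each library were whole multiples of its commonest low value, within a tolerance of 0.01. That lowest step was used to estimate unscaled fragments per library.

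The table lists genes by symbol. Of these symbols, 24017 matched GENCODE release 29 by name, 742 by an older name and 1281 not at all. Positions, exons, spliced length and GC were taken from that annotation, while the values stayed under the symbols of the table. Exons, spliced length and GC are those of the longest transcript of each gene in its basic set. That transcript need not be the mRNA measured. MLLT4 and other older symbols are printed as the table gives them.

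The samples formed 4 groups by shRNA and treatment. The comparisons were nutlin-3a against untreated in the shARVCF lines, the same in the control line, shARVCF against control lines under nutlin-3a, the same without drug, and the difference of the 2 nutlin-3a effects. Because the values are not counts, the count-based test intended for whole counts was replaced by its stated fallback, limma on log2 values with a pseudocount of 1. Genes with a value of at least 10 in at least 3 libraries were kept, 14955 in all. A single linear model with 4 group means was fitted to the 10 libraries, with 6 residual degrees of freedom, and variances were moderated with a trend on expression and robust weights (limma 3.58.1, R 4.3.3). All tests were two-sided and adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, called at 0.05. Fold changes are on the scale with the pseudocount, which shrinks them for genes near 0. Group means and SDs are of the scaled values. The lone untreated control library adds no spread of its own and was assumed to vary like the other groups.

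Groups, comparisons, tests, gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined. ARVCF, MDM2 and CDKN1A were named in every comparison. Per comparison, the 10 highest and 10 lowest log2 fold changes could be named among called genes with a mean of at least 50 and full separation of the libraries, printed from the top of each rank. For the difference of effects, each shRNA line had to lie on the same side of the control effect in the first library series. Genes without a named symbol, antisense and host genes, microRNAs, snoRNAs and pseudogenes were left out. From each list up to 4 members with the smallest adjusted p could be named, and any member standing alone against its list. Genes outside the rule are marked as named after their values were seen. A few genes that the rule takes, and 1 of the lists, are not reported here.

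The 27 gene lists cover p53 targets, replication, mitosis, histones, adhesion, splicing, interferon, inflammation, extracellular matrix, epithelial and mesenchymal genes, osteoblast and blood cell markers, signalling targets, metabolism, stress responses, ribosome, respiratory chain and lysosome. The list of mitochondrially encoded genes had too few measured members and is not analysed here. Each of the other lists was tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted over all lists and 5 comparisons, and again with an estimated correlation. No list was called with an estimated correlation (smallest adjusted p = 0.14). For the p53 lists the median response per line was set against 10000 random lists drawn from 10 expression bins.

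Alternatives were other pseudocounts (0.1 and 10), no filter, a filter of 1 in 1e6 of the library total in 3 libraries, 3 other scalings, a fold threshold, library series as a term, the first series alone, each library left out, and a replicate block on line. After the data had been seen, a correction that removes each library's trend with spliced length and GC (splines with 4 degrees of freedom, 14746 genes) and a fit without genes of 16-fold or wider range within a group were added. The list tests were run after that correction with the preset and the estimated correlation. Matched random lists for length and GC used 20 length bins and 10 GC bins. Residuals of the shARVCF libraries correlated most with those of the same line under the other treatment (r 0.275, 0.288 and 0.327, across genes), so replicate numbers pair those libraries. Control and shARVCF libraries share only a number (r 0.026, -0.022 and 0.045), and with 1 control line no pairing was made. Replicates of a group correlated at 0.974 to 0.981 and none were duplicates.

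Simulated data of 14859 genes held 200 changed genes per comparison, or 400 for the difference of effects, all with a mean of at least 50. The pipeline was tested on these data for such genes only, not for genes nearer the filter. It recovered 98% of 4-fold and 85% of 2-fold changes with nutlin-3a in the shARVCF lines, 96% and 70% in the control line, 97% and 84% between lines under nutlin-3a, 96% and 68% without drug, and 92% and 56.5% for the difference of effects. Unchanged genes called numbered 10, 13, 13, 8 and 16. The simulated noise was independent and had the fitted spread of each gene in every library, the lone untreated control included. It held no differences between lines or library series. These numbers therefore check the code and are not an error rate for the real libraries. A trend linear in annotated length was also added to the simulated control nutlin-3a libraries. Between lines under nutlin-3a, 3958 unchanged genes were then called before the correction and 15 after it (14659 genes). The correction was given the same length that made the trend. The result checks the code and not the case of mRNAs whose length differs from the annotation.

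Scaled totals ran from 17821751 to 19903778 per library and estimated fragments from 15073578 to 21096205, the lowest in replicates 2 and 3 of the nutlin-3a control. Between 17229 and 18569 genes were above 0, and the top 10 genes took 4.46% to 5.94% of the total. No counting interval is given since the values are not counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for annotation and figures.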

Results

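The data are RNA sequencing profiles of 10 libraries of U2OS, a human osteosarcoma cell line. Cells carried 1 of 3 shRNAs against ARVCF, a catenin of the p120 family that binds cadherins at cell junctions, or a negative control shRNA. They were left untreated or given 10 µM nutlin-3a for 24 h, a small molecule that frees the transcription factor p53 from MDM2, the ubiquitin ligase that degrades it. The series asks how loss of ARVCF changes transcription driven by p53. There was 1 untreated control library and 3 nutlin-3a control libraries, all from 1 control line. There were 3 untreated and 3 nutlin-3a shARVCF libraries, with each replicate number standing for a line with its own shRNA. Replicates 2 and 3 of the nutlin-3a control carry later library numbers and were taken as a second library series, with the other 8 libraries as the first. The series is inferred from these numbers alone, as no label names it. Scaled totals ran from 17821751 to 19903778 fragments per library, and estimated unscaled totals from 15073578 to 21096205. The first principal component held 65.9% of the variance and set treated apart from untreated libraries. Untreated libraries stood at -91.531 to -77.001 on it. Control nutlin-3a libraries stood at 87.676 to 95.575, but shARVCF nutlin-3a libraries only at 18.122 to 21.724. The second component held 15.3% and also set the shARVCF nutlin-3a libraries apart from the control nutlin-3a libraries.

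ARVCF itself (human genome build hg38, chromosome 22, 19969896 to 20016808, minus strand, 20 exons) was lower in the shARVCF lines under both conditions, and nutlin-3a raised it in both kinds of line. It stood at 617.7 scaled fragments in the untreated control library and at 324.3 ± 28.3 (SD, n = 3) in the untreated shARVCF libraries, which read 291.8, 343.2 and 338.0. Under nutlin-3a it stood at 2625 ± 280 in the control line, with libraries at 2928, 2571 and 2376, and at 1235 ± 48.3 in the shARVCF lines, with libraries at 1284, 1188 and 1232. The nutlin-3a rise was 3.81-fold in the shARVCF lines (adjusted p = 2.53e-08) and 4.23-fold in the control line (adjusted p = 2.81e-07). Under nutlin-3a the shARVCF lines held 2.12-fold less than the control line (log2 -1.08, SE 0.11, adjusted p = 3.14e-06), and each of the 3 was below each control library. Without drug the difference was log2 -0.93 (SE 0.15), lower in 3 of 3 libraries, with an adjusted p of 0.0957 that missed the threshold. The 2 nutlin-3a effects on ARVCF differed by log2 -0.15 (adjusted p = 0.564).

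**Figure D1:**
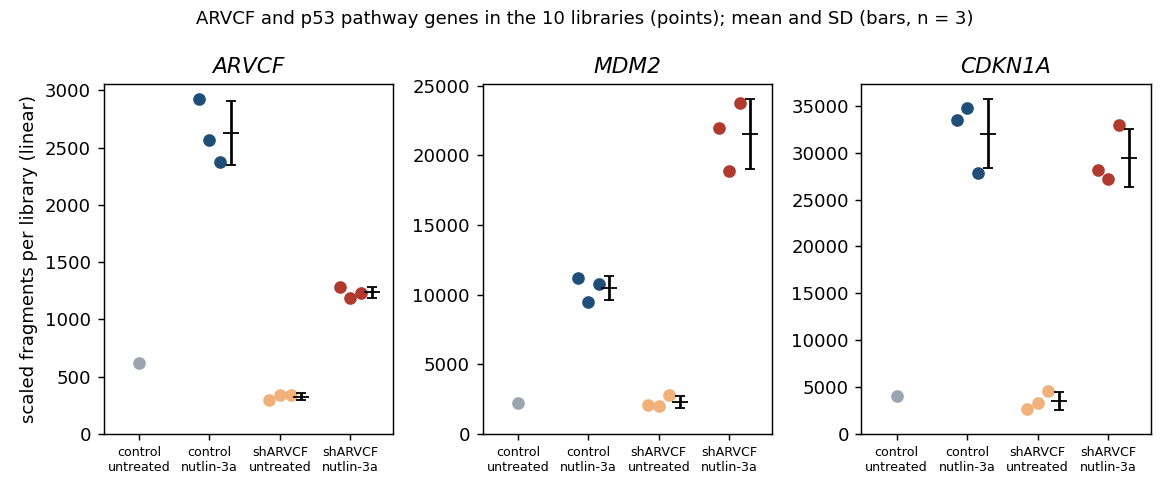
Scaled fragments of ARVCF, MDM2 and CDKN1A in each of the 10 libraries (linear axes), with points for libraries and bars for the mean and SD of groups with n = 3. ARVCF is at 617.7 in the untreated control library and at 324.3 ± 28.3 in the untreated shARVCF libraries.

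In the 3 shARVCF lines, nutlin-3a raised p53 target genes and lowered genes of DNA replication and mitosis. MDM2 rose 9.49-fold, from 2286 ± 435 to 21550 ± 2500 scaled fragments (SD, n = 3; log2 3.25, SE 0.13, adjusted p = 3.37e-09). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 8.64-fold, from 3482 ± 962 to 29440 ± 3060 (log2 3.11, SE 0.17, adjusted p = 6.74e-08). Both genes rose in 3 of 3 lines. The highest rises among genes past the named-gene rule were those of TREM2, a lipid-sensing receptor of myeloid cells (88.2-fold, adjusted p = 8.7e-05), the cornified envelope gene LCE1B (73.4-fold, adjusted p = 3.22e-06) and CLCA2, a regulator of calcium-activated chloride channels (71.8-fold, adjusted p = 4.78e-06). TREM2 went from 13.12 ± 10.1 to 971.5 ± 168. LCE1B has close paralogs, so its value is uncertain. The deepest falls were those of the zinc finger gene ZNF519 (90.0-fold, adjusted p = 0.0029), CENPA, the histone variant of centromeres (78.4-fold, adjusted p = 0.00124), and FAM111B, which encodes a protease (72.6-fold, adjusted p = 1.29e-08). CENPA went from 828.4 ± 96.7 to 12.96 ± 13.1.

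Of 64 measured p53 targets of arrest and feedback, 60 were called in the shARVCF lines and 56 of these rose, with a list median of log2 1.65. The list test gave an adjusted p of 6.2e-26, but adjusted p = 0.306 with an estimated correlation. TP53I3, TP53INP1, an autophagy and stress gene, and CYFIP2 rose by log2 2.82, 2.59 and 2.53. TP73, a p53 paralog, went against the list at log2 -3.24 (adjusted p = 5.1e-07) and was named after its values were seen. Among 21 apoptosis targets, 17 rose (median 1.68, list adjusted p = 1.25e-10, and adjusted p = 0.47 with an estimated correlation), among them the death receptor gene FAS (2.73) and the BCL2-family gene BBC3 (2.36). SIVA1, an apoptosis regulator named as the single member that fell, changed by log2 -1.09 (adjusted p = 0.000353). Of 58 DNA replication genes, 57 fell and 0 rose (median -3.51, list adjusted p = 3.93e-37, and adjusted p = 0.306 with an estimated correlation), among them the helicase subunits MCM5 (-3.22) and MCM7 (-2.83) and the polymerase POLE (-3.63). PCNA, the replication clamp, was not called (log2 -0.16, adjusted p = 0.282). All 72 mitosis genes fell (median -4.85, list adjusted p = 8.81e-48, and adjusted p = 0.316 with an estimated correlation), among them CENPF, a kinetochore protein (-4.79), CCNA2, cyclin A (-4.79), and ANLN, which acts in cytokinesis (-4.18).

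Lysosome and autophagy genes, inflammatory genes and YAP targets also moved in the shARVCF lines. Of 31 lysosome genes, 24 were called and 23 of these rose (median 0.70, list adjusted p = 7.28e-08, and adjusted p = 0.47 with an estimated correlation), among them DRAM1, also on the list of p53 targets (2.29), and the cathepsin gene CTSL (1.39). Of 24 NF-kB and secretory genes, 13 were called and 12 rose (median 0.56, list adjusted p = 0.00144, and adjusted p = 0.554 with an estimated correlation), among them the cytokine LIF (1.14). Of 20 YAP and TAZ targets, 14 were called and 12 rose (median 0.63, list adjusted p = 0.000613, and adjusted p = 0.47 with an estimated correlation), among them CYR61 (1.82). Of 23 TGF-beta targets, 15 were called and 10 rose (median 0.28, list adjusted p = 0.0231, and adjusted p = 0.387 with an estimated correlation). Of 24 cholesterol synthesis genes, 10 were called and 8 rose (median 0.25, list adjusted p = 0.0421, and adjusted p = 0.81 with an estimated correlation). Of 64 splicing factors, 46 were called and 43 fell (median -0.51, list adjusted p = 2.31e-08, and adjusted p = 0.306 with an estimated correlation), among them SRSF2 (-1.30) and SRSF7 (-1.02). Of 13 replication-dependent histone genes, 9 fell and 0 rose (median -1.02, list adjusted p = 0.0248, and adjusted p = 0.631 with an estimated correlation), among them HIST2H2AC (-2.58) and HIST1H2BJ (-1.29). Histone mRNAs of this kind mostly lack a poly(A) tail, so their values in poly(A) RNA may also reflect RNA selection. The ribosomal protein list was called as higher (median 0.14, list adjusted p = 0.0208, and adjusted p = 0.855 with an estimated correlation) although 66 of its 70 members were not, and it was not called after each library's trend with transcript length and GC was removed (list adjusted p = 0.131). Adjusted over the list alone, the counts were unchanged for both p53 lists, replication and mitosis, 25 lysosome, 13 inflammatory, 12 TGF-beta, 12 YAP and 8 cholesterol genes rose, and 44 splicing and 10 histone genes fell.

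By limma with Benjamini-Hochberg adjustment, 6394 of 14955 genes were called in the shARVCF lines, 3147 higher and 3247 lower with nutlin-3a. The larger side turned with other settings, to 3542 higher and 2904 lower with upper-quartile factors, 3236 and 3189 with relative log expression factors, and 3606 and 3052 after each library's trend with transcript length and GC was removed. All 6 libraries of this comparison belonged to the first library series, and the fit on that series alone called 6468 genes. With each line as a block the count was 7157 (3539 higher, 3618 lower). Each p-value measures the spread between these libraries, which may be technical as well as biological.

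In the control line, nutlin-3a raised p53 targets and lowered replication and mitosis genes as well. The treated libraries of this line also held more mRNA of ribosomal and respiratory chain genes. They carried a trend with transcript length whose origin stays open, so that rise cannot be credited to the drug. MDM2 rose 4.66-fold, from 2244 to 10480 ± 879 (SD, n = 3; log2 2.22, SE 0.19, adjusted p = 1.22e-06). After each library's trend with transcript length and GC was removed, its rise was log2 3.37 (SE 0.19) in this line, beside 3.23 in the shARVCF lines. CDKN1A rose 7.97-fold, from 3999 to 32030 ± 3690 (log2 3.00, SE 0.24, adjusted p = 1.45e-06). Each was higher in 3 of 3 treated libraries against the untreated library. Among the largest rises, LCE1C was listed at 0 in the untreated library and at 641.9 ± 87.1 with nutlin-3a, and TREM2 went from 5.482 to 2518 ± 487 (adjusted p = 8.36e-05). LCE1C shares sequence with its paralogs and is uncertain. The largest falls were those of the kinesin genes KIF15 and KIF14 and of PLK4, a kinase of centriole duplication. KIF15 went from 1328 to 2.866 ± 2.73 (adjusted p = 2.46e-07) and KIF14 from 1636 to 5.454 ± 2.64 (adjusted p = 1.01e-07). PLK4 went from 1100 to 3.733 ± 1.2 (adjusted p = 1.75e-08). Once the length and GC trend was removed, KIF15, KIF14 and PLK4 stood at log2 -7.78, -6.90 and -7.09. BUB1B (-7.19) and NEIL3 (-7.31) then fell further than KIF14 and PLK4.

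Of 64 arrest and feedback targets, 56 were called in the control line and 53 of these rose (median log2 1.67, list adjusted p = 5.34e-17, and adjusted p = 0.387 with an estimated correlation), among them TP53I3 (3.72), GADD45A, a growth arrest and DNA damage gene (3.64), and FDXR, a mitochondrial reductase (3.49). TP73 fell by 3.87 on the log2 scale and was named after its values were seen. Of 21 apoptosis targets, 16 rose (median 1.69, list adjusted p = 1.33e-07, and adjusted p = 0.474 with an estimated correlation), among them FAS (2.48) and BAX, a pore-forming BCL2-family member (1.90). APAF1, the apoptosome scaffold, was the single apoptosis target that fell (log2 -0.98, adjusted p = 0.00276), and after the length and GC trend was removed its value was 0.06 (adjusted p = 0.86). BAX then stood at 1.13, CENPF at -5.48, ANLN at -5.30, SMC2 at -3.13 and FDXR at 2.79. Of 58 replication genes, 57 fell and 0 rose (median -4.11, list adjusted p = 4.81e-22, and adjusted p = 0.397 with an estimated correlation), among them POLE (-4.70), UHRF1 (-3.58) and MCM5 (-3.01). PCNA was not called (log2 0.28, adjusted p = 0.152), but it was with upper-quartile scaling (log2 0.42, adjusted p = 0.035). All 72 mitosis genes fell (median -5.81, list adjusted p = 1.26e-31, and adjusted p = 0.397 with an estimated correlation), among them CENPF (-6.65), ANLN (-6.20) and the condensin gene SMC2 (-4.25).

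Of 70 cytosolic ribosomal protein genes, 69 rose in the control line and 0 fell (median 1.09, list adjusted p = 2.65e-19, and adjusted p = 0.47 with an estimated correlation). RPS20 rose by log2 1.42, from 14390 to 38660 ± 2750. Of 35 oxidative phosphorylation genes, 24 rose (median 0.57, list adjusted p = 1.4e-05, and adjusted p = 0.579 with an estimated correlation), among them COX7A2 (1.22) and NDUFB8 (1.26). NDUFS1, a subunit of complex I, was the single member that fell (log2 -0.79, adjusted p = 0.000193), and after the length and GC trend was removed it stood at 0.35 (adjusted p = 0.0334). Of 31 lysosome genes, 24 were called and 23 rose (median 0.87, list adjusted p = 1.44e-06, and adjusted p = 0.515 with an estimated correlation), among them the cathepsin gene CTSD (1.38). Of 24 NF-kB and secretory genes, 9 were called and 8 rose (median 0.72, list adjusted p = 0.0317, and adjusted p = 0.746 with an estimated correlation), and the list was not called once the trend was removed (list adjusted p = 0.0626). Of 18 Wnt targets, 14 were called and 12 fell (median -1.19, list adjusted p = 0.0311, and adjusted p = 0.47 with an estimated correlation), among them the feedback inhibitor NKD1 (-2.39) and the transcription factor SOX4 (-2.02). Of 64 splicing factors, 38 were called and 34 fell (median -0.41, list adjusted p = 0.00355, and adjusted p = 0.47 with an estimated correlation), among them MBNL1 (-3.19) and DDX17 (-1.48). Once the trend was removed the splicing list was not called (median -0.07, 10 higher and 20 lower, list adjusted p = 0.231), MBNL1 stood at -2.12 and DDX17 at -0.78. NDUFB8 then stood at 0.53, CTSD at 0.74 and NKD1 at -1.67, and 50 ribosomal and 19 oxidative phosphorylation genes were higher. Adjusted over the list alone, 54 arrest targets rose, 13 Wnt targets fell, and the counts of members that rose in the ribosomal, respiratory chain, lysosome, inflammatory and apoptosis lists and that fell in the replication, mitosis and splicing lists were the same.

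In the control line 8532 genes were called, 3752 higher and 4780 lower. The larger side turned to 4497 higher and 4190 lower with upper-quartile factors and to 4236 and 3107 once the length and GC trend was removed, and with library size alone it was 3275 and 5332. The lone untreated library was assumed to vary like the other groups. The change also went with spliced transcript length in this line (Spearman's rho -0.43 across genes, which are not independent replicates, against -0.03 in the shARVCF lines). The first library series alone, with 1 treated and 1 untreated control library, gave 7359 genes, and a fit with series as a term gave 7493.

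The nutlin-3a responses of the 2 kinds of line shared much of their content. Of the genes called in both, 1963 were higher in both, against 789.5 if the calls were independent, and 2327 were lower in both, against 1037.8, while 369 went opposite ways. Both sets of calls share the same fit and the same spread per gene, so they are not independent. The numbers for independent calls are therefore a low reference. Among genes of at least 2-fold change, 803 were higher in both, 1048 lower in both and 9 opposite. Across 14955 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.76 and a Spearman's rho of 0.64. The median rise of the arrest and feedback targets was log2 1.66, 1.62 and 1.56 in shARVCF lines 1, 2 and 3, and 1.66, 1.58 and 1.66 in control nutlin-3a libraries 1, 2 and 3. For the apoptosis targets it was 1.56, 1.59 and 1.49 in the shARVCF lines and 1.73, 1.74 and 1.59 in the control libraries. Every one of these medians stood at percentile 100 of 10000 random lists matched on expression.

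**Figure D2:**
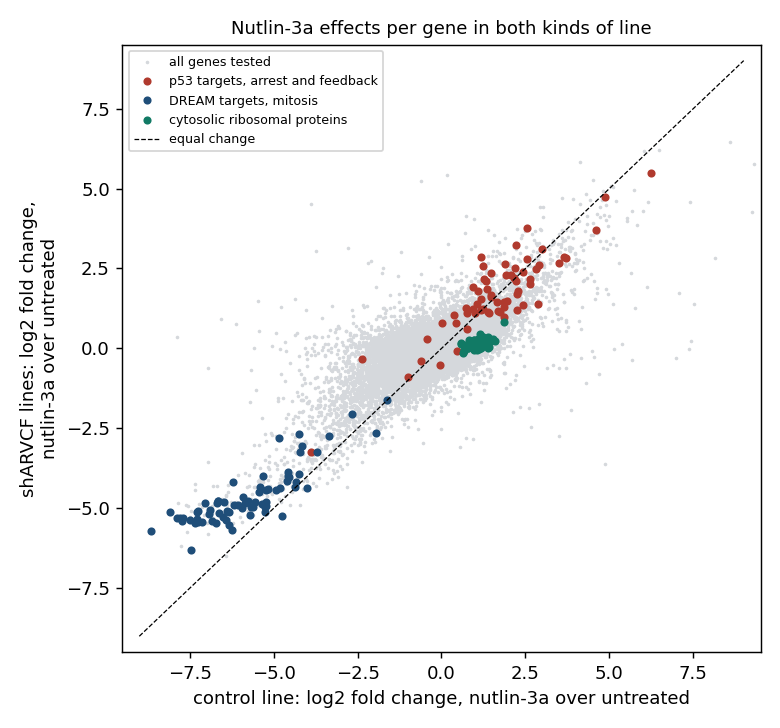
Log2 fold change with nutlin-3a of each of 14955 genes in the control line (x axis) and in the shARVCF lines (y axis), with all genes in grey, arrest and feedback targets in red, mitosis genes in blue and ribosomal protein genes in green. The dashed line marks equal change, and the medians of the red genes are 1.67 on the x axis and 1.65 on the y axis.

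Under nutlin-3a, the shARVCF lines held more mRNA of mitosis genes and less of ribosomal and respiratory chain genes than the control line. Their p53 targets differed in both directions. All 3 control libraries came from 1 line, so the p-values of this comparison do not measure the spread between control lines. MDM2 was 2.05-fold higher, at 21550 ± 2500 against 10480 ± 879 (SD, n = 3 each; log2 1.04, SE 0.13, adjusted p = 3.19e-05), but once each library's trend with transcript length and GC was removed it was not called (log2 -0.16, SE 0.14, adjusted p = 0.374). CDKN1A did not pass the test, at 29440 ± 3060 against 32030 ± 3690 (log2 -0.12, SE 0.17, adjusted p = 0.574). SFN, the 14-3-3 sigma gene of cell-cycle arrest, was lower at 12930 ± 1560 against 41190 ± 568 (log2 -1.68, SE 0.12, adjusted p = 3.01e-07). ACER2, a ceramidase gene, was higher at 716.6 ± 57.1 against 253 ± 17.3 (log2 1.498, SE 0.15, adjusted p = 3.72e-06). Of 64 arrest and feedback targets, 18 were higher and 20 lower, also when adjusted over the list alone, and the list was not called (median -0.01, mean 0.03, test direction down, adjusted p = 0.663). Its median was 0.11 with library size alone as the scaling. TP53I3 (-0.98) was among the lower targets and TP53INP1 (0.97) among the higher. Of 21 apoptosis targets 14 were called and 10 were lower, the same 10 by count when adjusted over the list alone (median -0.23, list adjusted p = 0.131), with BAX (-0.86) and BAK1 (-0.92) lower and APAF1 (1.44) higher. The calls of TP53INP1 (0.09, adjusted p = 0.567) and BAX (-0.13, adjusted p = 0.272) ended once that trend was removed.

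Of 72 mitosis genes, 54 were higher in the shARVCF lines under nutlin-3a (median 1.04, list adjusted p = 5.09e-08, and adjusted p = 0.713 with an estimated correlation), among them ASPM, a spindle pole protein (2.47), ANLN (2.07) and CENPF (1.98). PTTG1, securin, was the single mitosis gene that was lower (log2 -0.73, adjusted p = 0.0163), and its call ended without control nutlin-3a replicate 1 or shARVCF nutlin-3a replicate 2 (adjusted p 0.0604 to 0.0622), with the first library series alone (adjusted p = 0.0951) and after the length and GC trend was removed (adjusted p = 0.153). Of 70 ribosomal protein genes, 69 were lower and 0 higher (median -0.94, list adjusted p = 3.35e-22, and adjusted p = 0.47 with an estimated correlation), among them RPLP2 (-1.38), RPL23 (-1.05) and RPS15A (-1.03). Against the control library of the first series the ribosomal median was -1.06, and against those of the second it was -0.84. Of 35 oxidative phosphorylation genes, 29 were lower (median -0.73, list adjusted p = 3.29e-09, and adjusted p = 0.47 with an estimated correlation), among them COX7A2 (-1.11) and COX5B (-1.04). NDUFS1 was the single member that was higher (log2 0.66, adjusted p = 4.68e-05), and it was lower after the length and GC trend was removed (log2 -0.51, adjusted p = 0.000608). Of 31 cadherin and catenin genes, 21 were called and 17 were higher (median 0.65, list adjusted p = 0.036, and adjusted p = 0.47 with an estimated correlation), among them the desmosome genes DSG2 (1.64) and PKP2 (1.31) and VCL, vinculin (0.96). After the trend was removed VCL lost its call (0.23, adjusted p = 0.0522) and so did the cadherin list (median 0.05, list adjusted p = 0.47). Adjusted over the list alone, 55 mitosis and 17 cadherin genes were higher and 69 ribosomal and 30 oxidative phosphorylation genes lower.

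**Figure D3:**
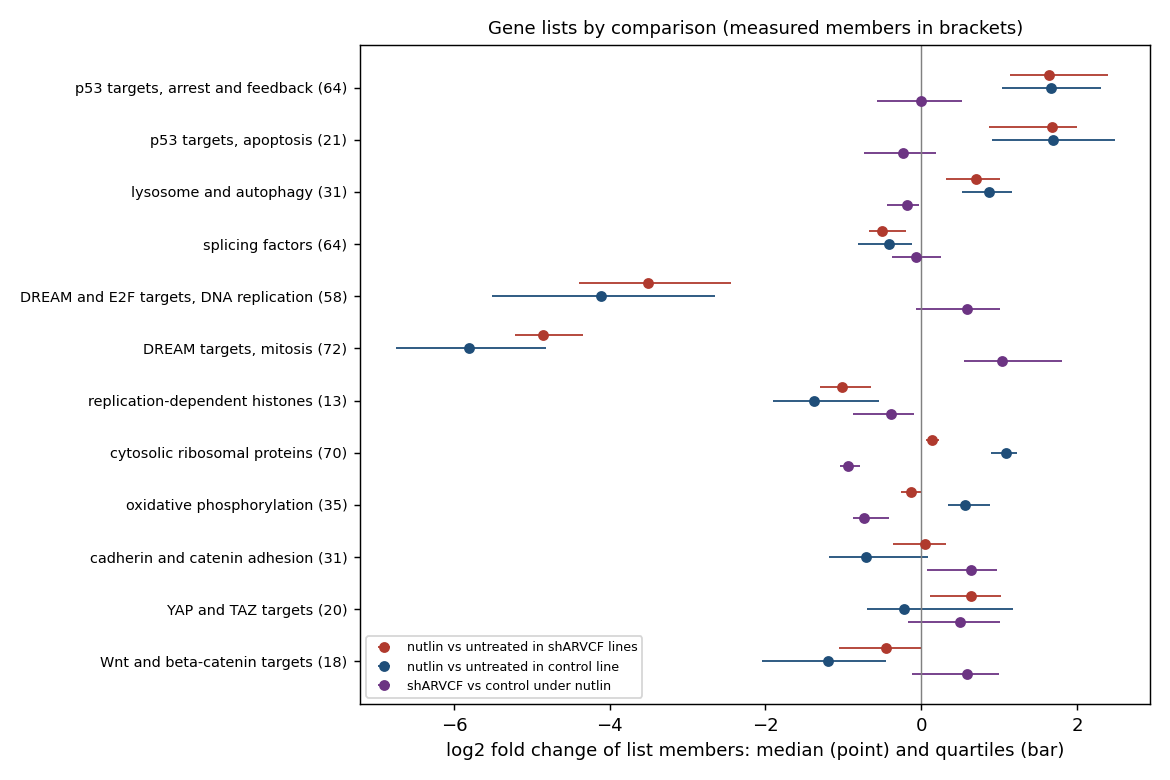
Median (point) and quartiles (bar) of the log2 fold change of the members of 12 gene lists with nutlin-3a in the shARVCF lines, with nutlin-3a in the control line, and in shARVCF against control lines under nutlin-3a. Ribosomal protein genes have medians of 0.14, 1.09 and -0.94 in these comparisons.

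The highest differences past the named-gene rule between shARVCF and control lines under nutlin-3a were those of ERCC6-PGBD3, listed at about 0 in the control line and at 243.7 ± 29 in the shARVCF lines, PALM2-AKAP2 (log2 6.42, SE 1.37, adjusted p = 0.00667) and BIVM-ERCC5 (log2 6.22, SE 1.82, adjusted p = 0.0243). JMJD7-PLA2G4B (log2 5.45, adjusted p = 8.56e-05) came next. These are read-through genes that overlap their neighbours, so their values are uncertain, and control libraries of BIVM-ERCC5 stood at 38.1 ± 66. PALM2-AKAP2 and BIVM-ERCC5 ranged over log2 6.005 and 6.849 within a group, so both are among the genes of 16-fold or wider range. The call of BIVM-ERCC5 ended without control nutlin-3a replicate 1 or 3 or any of shARVCF nutlin-3a replicates 1, 2 and 3 (adjusted p 0.0586 to 0.0675), and after the length and GC trend was removed (adjusted p = 0.0552). ARID2, a subunit of a chromatin remodelling complex, was 31.1-fold higher, at 1191 ± 158 against 46.2 ± 30.6 (log2 4.96, SE 0.57, adjusted p = 0.000229). The lowest were IPO11-LRRC70, another read-through (log2 -7.37), and TIAF1, which lies within another gene and is uncertain (log2 -5.12, adjusted p = 3.23e-06). PGBD3 and LCE1C, both uncertain for shared sequence, followed at log2 -2.54 and -2.43. YBX2, a germ cell RNA-binding protein gene, stood at 18.39 ± 8.84 against 97.1 ± 14.5 (log2 -2.42, adjusted p = 3.29e-05). BCL2A1, an anti-apoptotic BCL2-family gene, stood at 69.63 ± 42.5 against 317.4 ± 46.7 (log2 -2.33, adjusted p = 0.000211).

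In this comparison 8731 genes were called, 4829 higher and 3902 lower in the shARVCF lines. Chance separates 3 against 3 libraries in 10% of cases. The difference rose with spliced transcript length (Spearman's rho 0.58 across genes) and fell with GC (rho -0.52). Its median was log2 -0.60 in the shortest of 5 equal length classes and 0.83 in the longest. The longest annotated transcript of MDM2 has 12633 bases and that of SFN 1320, which need not be the mRNA measured. The corrected value of a gene, that of MDM2 included, depends on this choice of transcript. Once each library's trend with length and GC was removed, 5731 genes were called, 2334 higher and 3397 lower. As given above, MDM2, TP53INP1 and BAX were then not called. Of the targets that stayed called, SFN was at -0.83, TP53I3 at -0.43, BAK1 at -0.41, APAF1 at 0.48 and ACER2 at 1.53. RPS27L, BLOC1S2 and TNFRSF10C, named after their values were seen, moved further from 0, from -0.46, -0.67 and 1.77 to -1.32, -0.95 and 2.39. FBXO22, also named after its values were seen, went from -0.08 to -1.33 (adjusted p = 1.41e-06 after the correction). The longest annotated transcripts of RPS27L and FBXO22 have 6434 and 10725 bases, and the correction takes more from long transcripts. Such enlarged values depend on that length and need not be effects that the trend had hidden. The call of RPS27L before the correction ended without shARVCF nutlin-3a replicate 1 (adjusted p = 0.0618). Of the arrest targets 6 were then higher and 14 lower, and of the apoptosis targets 3 were higher and 6 lower. BBC3, named after its values were seen, turned from -0.52 to 0.32 (adjusted p = 0.0427). ASPM then stood at 1.20, ANLN at 1.31, CENPF at 0.82, RPLP2 at -0.54 and DSG2 at 0.80. ARID2 stood at 3.87, LCE1C at -1.61 and YBX2 at -1.63. With the first library series alone, which leaves 1 control nutlin-3a library, 6650 genes were called (3791 higher, 2859 lower), and with series as a term 6730. The ribosomal, oxidative phosphorylation and mitosis lists after the trend was removed had medians of -0.60, -0.501 and 0.91, with 56 lower, 26 lower and 42 higher. Of the splicing genes, 16 higher and 19 lower before, 36 were then called and 32 were lower (median -0.33, list adjusted p = 0.0036, and adjusted p = 0.605 with an estimated correlation).

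**Figure D4:**
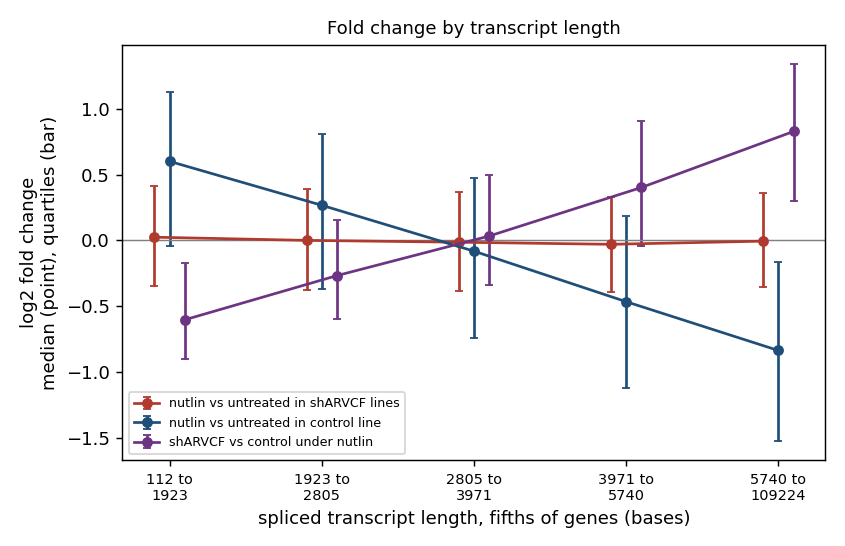
Median (point) and quartiles (bar) of the log2 fold change of genes in 5 equal classes of spliced transcript length, for nutlin-3a in the shARVCF lines, nutlin-3a in the control line, and shARVCF against control lines under nutlin-3a. In the last, the medians run from -0.60 in the shortest class to 0.83 in the longest, and in the control line from 0.60 to -0.83.

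Without nutlin-3a, limma called 3 of 14955 genes between the shARVCF lines and the lone control library, all higher, and 237 at an unadjusted p under 0.05. They are LOC100128361 at a mean of 41.1, PGBD3 at 35.5 and the synaptotagmin gene SYT16 at 20.1, each listed at about 0 in the control library, so no fold is given. They were named after their values were seen, with adjusted p of 0.015, 0.00563 and 0.0263. PGBD3 shares exons with ERCC6 and is uncertain. The call of SYT16 ended without control nutlin-3a replicate 1, 2 or 3 or without shARVCF untreated replicate 1 (adjusted p 0.0815 to 0.104), and with a pseudocount of 10 none of the 3 genes was called. MDM2 and CDKN1A stood at 2286 ± 435 and 3482 ± 962 in the shARVCF lines against 2244 and 3999 in the control, and neither passed the test. The first library series holds all 4 untreated libraries, and fitted alone it called 0 genes.

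No member of any list passed the test over all genes in the untreated libraries. Replication-dependent histone genes had a list median of -0.67 (list adjusted p = 2.11e-09, and adjusted p = 0.316 with an estimated correlation), with HIST2H2BE at -0.87 (adjusted p = 0.103) and HIST1H1C at -0.84 (adjusted p = 0.774), which were both past the threshold when adjusted over the list alone. Most of these mRNAs lack a poly(A) tail, so in poly(A) RNA this difference may reflect RNA selection and not expression. TGF-beta targets had a median of -0.18 (list adjusted p = 7.34e-07, and adjusted p = 0.14 with an estimated correlation), with ID3 at -0.68 and TPM1 at -0.46. Epithelial genes had a median of -0.36 (list adjusted p = 0.0238, and adjusted p = 0.47 with an estimated correlation). Interferon response genes had a median of 0.22 (list adjusted p = 2.2e-05, and adjusted p = 0.768 with an estimated correlation), with PARP12 at 0.55 and STAT2 at 0.28. Integrated stress response genes had a median of 0.18 (list adjusted p = 0.000128, and adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, 0 members of these last 4 lists passed. With 1 control library, each list value rests on that library. Across genes the difference without drug fell with GC (Spearman's rho -0.305), but hardly changed with spliced length (rho 0.006).

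The difference of the nutlin-3a effects asks whether a gene answered the drug otherwise in shARVCF lines than in the control line. The log2 difference of MDM2 was 1.03 (adjusted p = 0.00542), but -0.14 and not called once the length and GC trend was removed (SE 0.24, adjusted p = 0.777). CDKN1A (0.12, adjusted p = 0.802) did not pass the test. MAP3K1, a kinase of stress signalling, was at 525.6 in the untreated control and 22.35 ± 4.5 with nutlin-3a, but at 524.1 ± 27.4 and 382.3 ± 22.9 in the shARVCF lines. REL, an NF-kB subunit, went from 556.7 to 35.23 ± 13.9 in the control line, and stood at 585.3 ± 38.3 and 520.4 ± 50.1 in the shARVCF lines. S100A2, a calcium-binding protein gene, went from 3576 to 27210 ± 1520 in the control line and from 3663 ± 429 to 7233 ± 334 in the shARVCF lines. Of 64 arrest and feedback targets, the difference was above 0 for 11 called and below 0 for 9, the same counts as adjusted over the list alone, with a median of 0.08 and a test direction of down (list adjusted p = 0.793). TP53INP1 (1.35) and ACER2 (1.68) were above 0, and SFN (-1.47) and TP53I3 (-0.90) below. Of 21 apoptosis targets 6 were called (median -0.31, list adjusted p = 0.169), among them APAF1 (1.55). Once the length and GC trend was removed, 6 arrest targets were called, 2 higher and 4 lower (median -0.09). The apoptosis list then held 0 called targets (median -0.15). The median of the arrest list was -0.001 with upper-quartile scaling.

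Of 72 mitosis genes, 32 fell less in the shARVCF lines and 0 fell more (median 1.05, list adjusted p = 1.77e-07, and adjusted p = 0.741 with an estimated correlation), among them ANLN (2.02) and SMC2 (1.56). Of 70 ribosomal protein genes, 62 were lower and 0 higher (median -0.91, list adjusted p = 1.98e-24, and adjusted p = 0.47 with an estimated correlation), among them RPS15A (-1.07) and RPS20 (-1.19). Of 35 oxidative phosphorylation genes, 23 were called and 22 were lower (median -0.74, list adjusted p = 2.01e-10, and adjusted p = 0.47 with an estimated correlation), among them COX7A2 (-1.15). Of 31 cadherin and catenin genes, 17 were called and 15 were higher (median 0.72, list adjusted p = 0.018, and adjusted p = 0.397 with an estimated correlation), among them DSG2 (1.69). Of 20 YAP and TAZ targets 9 were higher and 0 lower (median 0.63, list adjusted p = 0.0189, and adjusted p = 0.579 with an estimated correlation), among them PTPN14, a phosphatase that holds YAP back (2.13), and the kinase LATS2 (1.26). Of 18 Wnt targets 8 were higher and 0 lower (median 0.72, list adjusted p = 0.044, and adjusted p = 0.47 with an estimated correlation), among them AXIN2 (1.33) and SOX4 (2.02). Adjusted over the list alone, 37 mitosis, 16 cadherin, 11 YAP and 10 Wnt genes were higher and 68 ribosomal and 25 oxidative phosphorylation genes lower.

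The difference of effects was called for 4756 genes, 2893 higher and 1863 lower in the shARVCF lines, and for 5764 with each line as a block. It too rose with spliced length (Spearman's rho 0.58 across genes), and 1991 genes were called, 779 higher and 1212 lower, once each library's length and GC trend was removed. The call of MDM2 then ended, as given above, and the calls of TP53INP1 (0.52, adjusted p = 0.102), TP53I3 (-0.38, adjusted p = 0.125) and APAF1 (0.62, adjusted p = 0.196) ended too. SFN stood at -0.68, MAP3K1 at 3.15, REL at 2.68, S100A2 at -1.34, ANLN at 1.31, SMC2 at 0.66, DSG2 at 0.88 and PTPN14 at 1.04. The cadherin list then had a median of 0.04 and was not called (list adjusted p = 0.311). Of the other lists, 14 mitosis genes were higher, 31 ribosomal and 16 oxidative phosphorylation genes lower, and the median was 0.25 for YAP and 0.499 for Wnt targets. The YAP targets then called were AMOTL2 (0.70), CRIM1 (0.91), LATS2 (0.76) and PTPN14 (list adjusted p = 0.0124, and adjusted p = 0.605 with an estimated correlation). The Wnt targets then called were AXIN2 (1.07), LEF1 (0.85) and SOX4 (1.44), with EPHB2 (-0.63) and CD44 (-1.38) lower (list adjusted p = 0.0338, and adjusted p = 0.45 with an estimated correlation). AMOTL2, CRIM1, LEF1, EPHB2 and CD44 were named after their values were seen, and EPHB2 (0.05) and CD44 (-0.65) were not called before the correction. The first library series alone gave 3940 genes and series as a term 4112.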

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

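The test of how many calls the length and GC correction keeps, the test of the ribosomal median against each library series, and that correction itself were chosen after the result was seen. Each gene and list of the next paragraph is given because its nutlin-3a effect differed between the shARVCF lines and the control line in a test of the difference itself.

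That difference was called for 4756 genes. It was 1.03 on the log2 scale for MDM2, whose call ended after the length and GC correction (log2 -0.14, adjusted p = 0.777). Among the highest were 8.23 for ERCC6-PGBD3, 6.87 for JMJD7-PLA2G4B, 5.02 for ARID2, 4.30 for POTEE, 4.06 for MAP3K1, 3.92 for POTEF, 3.92 for ATXN1L, 3.86 for REL and 3.73 for FAM171B. The lowest were -7.37 for IPO11-LRRC70, -7.27 for PGBD3, -4.48 for TIAF1, -3.55 for LCE1C, -2.89 for BCL2A1, -2.35 for SYCE1L, -2.29 for MRPL23, -2.16 for SPANXC, -2.10 for SPOCD1 and -1.94 for S100A2. The read-through genes ERCC6-PGBD3, JMJD7-PLA2G4B and IPO11-LRRC70, and PGBD3, TIAF1, POTEE, POTEF and LCE1C, share sequence with other genes and are uncertain. The calls of SYCE1L (log2 -1.55, adjusted p = 0.0536) and MRPL23 (-1.47, adjusted p = 0.107) ended after the length and GC correction. ARID2 then stood at 3.97, ATXN1L at 3.18, FAM171B at 2.86 and LCE1C at -2.755, all still called. JMJD7-PLA2G4B (7.07) and TIAF1 (-4.93) moved further from 0. List medians were 1.05 for mitosis, 0.72 for cadherin and catenin genes, 0.63 for YAP and TAZ targets, 0.72 for Wnt targets, -0.74 for oxidative phosphorylation and -0.91 for ribosomal proteins. None of these lists was called with an estimated correlation (adjusted p = 0.741, 0.397, 0.579, 0.47, 0.47 and 0.47). After the correction these were 0.87, 0.04, 0.25, 0.499, -0.48 and -0.57, and the cadherin list was no longer called (list adjusted p = 0.311).

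Under nutlin-3a, ribosomal and oxidative phosphorylation genes were lower and mitosis genes higher in the shARVCF lines than in the control line. Random lists matched on annotated length and GC had medians near -0.364 for the ribosomal, -0.27 for the oxidative phosphorylation and 0.155 for the mitosis list. The real medians were -0.936, -0.728 and 1.041, further from 0 than the matched medians. The random lists draw unrelated genes, but members of the real lists are correlated (estimated at 0.473, 0.312 and 0.451). The real lists were also taken from the pattern itself. None was called with an estimated correlation (list adjusted p = 0.47, 0.47 and 0.713). The matching therefore cannot decide whether a trend with the annotated values is the whole cause. The annotated length is that of the longest transcript of a gene, not of the mRNA measured. A trend with the real mRNA length as the whole cause therefore cannot be excluded. Library series as the cause is argued against for the ribosomal list. Its median was -1.063 against the first-series control library and -0.835 against those of the second. The trend may account for most single calls, as 45.255% of the genes called before its removal stayed called in the same direction. Against the untreated control library, Spearman's rho with length was -0.448 in the first-series control nutlin-3a library and -0.406 and -0.415 in the second. In the shARVCF nutlin-3a libraries, each against its own line, it was -0.006, -0.032 and -0.03. Whether the trend arose in the cells or in RNA or library handling of the control nutlin-3a samples stays open, as does the knockdown against a trait of the 1 control line, which is a biological difference left untested.

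The p53 targets that differed between the lines under nutlin-3a went both ways. Over 79 targets the log2 difference rose with spliced length (Spearman's rho 0.565, Pearson's r 0.537, permutation p = 1e-05 for each, the smallest the permutations can give; genes are not independent replicates), so a length trend may underlie much of this split. Of 48 called targets, 20 were also called after the correction, 19 of them in the same direction, and 6 others were called only after it. Of the called targets, 97.917% kept their direction by more than 0.2 on the log2 scale against the first-series control library. These targets were chosen by a test that included that library, so this outcome was nearly fixed in advance. The share therefore cannot decide on library series as the cause. An effect of ARVCF on single targets stays open and was not tested beyond the 1 control line.

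Dividing the same 6 libraries in other ways gave 10 splits per comparison, too few for a share under 0.05. With nutlin-3a in the shARVCF lines, 1 split of the 10, the real one, gave as many as 6394 genes, and the highest other gave 2. The real split parts both libraries of each of 3 lines, as 3 other splits do, with at most 1 gene, and the remaining 6 part 1 line and keep the other libraries of a line together. Between shARVCF and control lines under nutlin-3a, 1 split, the real one, gave as many as 8731 genes, and the highest other gave 1. Every other split mixes the groups compared, which puts a large difference into the spread. Low counts in those splits follow from the mixing and give no measure of chance.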

How the results depend on the processing

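The length and GC correction, alone or with the first series, the block or an estimated correlation, and the fit without genes of 16-fold range were chosen after the data had been seen. Of 5322 pairs of a named gene and a setting, 5174 kept direction and call, 122 lost the call, 6 gained it and 20 turned direction. The correction with the first series alone moved most, as 30 of 54 named genes kept direction and call under nutlin-3a, 21 lost the call and 3 turned. With a fold threshold of 2, genes called fell to 2403 and 4990 for nutlin-3a in shARVCF and control lines, 3015 under nutlin-3a, 2257 for the difference of effects and 1851 shared, by construction. The correction gave 5731 genes under nutlin-3a (2334 higher, 3397 lower), 3337 with the first series alone as well, 1991 for the difference of effects and 2932 with the block too. Without drug, 8 genes were called with a pseudocount of 0.1, and 0 with a pseudocount of 10, the first series alone or the correction. Lists called fell from 12, 10, 4, 5 and 6 to 0 in each comparison with an estimated correlation, and were 8 under nutlin-3a with the correction (replication, mitosis, splicing, interferon, YAP, unfolded protein response, oxidative phosphorylation and ribosomal genes), but 0 in each comparison with both (smallest adjusted p = 0.256). The mean control arrest response was 1.716 with relative log expression factors and 1.517 with library size alone, against 1.635, and the apoptosis response 1.569 with library size, against 1.687. Median log2 changes of all genes moved from -0.096 to -0.215 in the control line and from 0.056 to 0.17 under nutlin-3a with library size alone, and to 0.041 in the control line with upper-quartile factors. Leaving out 1 library gave 5323 to 6603 and 8163 to 8568 genes for nutlin-3a in shARVCF and control lines, 7833 to 8725 under nutlin-3a, 4153 to 4830 for the difference, and 1 to 4 without drug, the 1 without shARVCF untreated replicate 1. ARVCF under nutlin-3a ran from -1.152 to -1.002. The lone untreated control library could not be left out for the control line, the untreated comparison or the difference. Their ranges therefore do not cover it.

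Turned directions were these. Under nutlin-3a, MDM2 was -0.164 with the correction and -0.241 with the first series too, CDKN1A 0.35 and 0.297, and NDUFS1 -0.512 and -0.631 likewise. Without drug, MDM2 was -0.028 with the correction and ran from -0.141 (without shARVCF untreated replicate 3) to 0.091 with libraries left out. For the difference of effects, MDM2 was -0.136 with the correction, with or without the block, and CDKN1A ran from -0.067 (without shARVCF untreated replicate 1) to 0.323. EPHB2 was -0.634 with the correction, with or without the block, -0.02 with relative log expression factors and -0.034 with upper-quartile factors, and ran from -0.038 (without control nutlin-3a replicate 1) to 0.131 with libraries left out. In the control line, APAF1 was 0.057 and NDUFS1 0.346 with the correction, with or without the block. The cause was not tested, except that the correction acts on length and GC alone. A block on replicate number called 8325 genes under nutlin-3a, against 8501 with the 6 nutlin-3a libraries alone. The planned count-based tests and their normalisation were not run, as the values are not counts. Depth was lowest in control nutlin-3a replicates 2 and 3, and limits calls for genes near 0.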

Other observations

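Some keratin and epithelial genes rose and others fell with nutlin-3a, while the epithelial list was not called in either kind of line (list adjusted p = 0.967 in the shARVCF lines, with 9 of 14 members not called, and 0.445 in the control line, with 8 not called). KRT17, a keratin of basal and stressed epithelia, rose by log2 1.36 in the shARVCF lines, from 11350 ± 2010 to 28730 ± 1400 (SD, n = 3; adjusted p = 2.37e-06), and by log2 2.54 in the control line, from 15440 to 89540 ± 3870 (adjusted p = 2.16e-07). KRT18, a keratin of simple epithelia, rose by log2 1.60 in the control line (adjusted p = 0.00111), and in that line KRT18 stood at 1.003, KRT17 at 1.78, KRT14 at -2.65 and CD34, a stem cell surface marker, at -1.98 once the length and GC trend was removed. KRT14, a basal keratin, fell in both, by log2 -2.49 (adjusted p = 0.000138) and -1.93 (adjusted p = 0.00524), as did the adhesion gene EPCAM, by log2 -1.16 and -1.21 (adjusted p = 0.00126 and 0.00612). Under nutlin-3a KRT17 and KRT8 were lower in the shARVCF lines (log2 -1.64 and -1.29, adjusted p = 4.48e-07 and 8.96e-06), or -0.89 and -1.07 once the length and GC trend was removed, while the epithelial list as a whole was not called (median -0.56, list adjusted p = 0.0841).

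Of 45 interferon response genes, 23 were called between shARVCF and control lines under nutlin-3a and 18 were higher in the shARVCF lines, or 15 when adjusted over the list alone, among them the ubiquitin ligase gene DTX3L (log2 1.48) and PARP14 (1.02). The list was not called (median 0.72, list adjusted p = 0.138), and once the length and GC trend was removed DTX3L stood at 0.69 and PARP14 was not called (0.06, adjusted p = 0.65), while the list was, with 9 members called and 7 of them higher (median 0.32, list adjusted p = 0.00894, and adjusted p = 0.823 with an estimated correlation). CD34 fell with nutlin-3a from 438.5 ± 174 to 73.49 ± 16.8 in the shARVCF lines (adjusted p = 7.98e-06) and from 409.4 to 56.02 ± 5.86 in the control line (adjusted p = 3.71e-05). The blood cell marker list was not called in any of the 5 comparisons (smallest adjusted p = 0.687). Of other lists never called before the correction, the smallest adjusted p was 0.0833 for extracellular matrix, 0.377 for mesenchymal transcription factors, 0.155 for osteoblast genes, 0.0769 for the unfolded protein response, 0.172 for hypoxia and glycolysis, and 0.0944 for NRF2 targets. After it, the unfolded protein response list was called under nutlin-3a, with 9 of 20 members lower (median -0.29, list adjusted p = 0.00894, and adjusted p = 0.684 with an estimated correlation).

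Of 12375 genes with a mean of at least 50, 44 (0.356%) ranged over 16-fold or more within a group. The metallothionein gene MT2A stood at 32540 ± 3040 in the control line under nutlin-3a and at 8260 ± 4040 in the shARVCF lines (log2 -2.10, adjusted p = 0.00105, and -1.19 once the trend was removed).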
